A study of Arabidopsis thaliana with 3 samples.

How the data were processed

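Genomic DNA from mature leaves of 3 Arabidopsis thaliana genotypes, dms4-1, sdr1-1 and dms4-1 sdr1-1, was sonicated, ligated to adaptors, bisulfite-converted, amplified by PCR and sequenced. Each genotype had 1 library and no wild-type library was analysed here. The deposited files give, for each cytosine and strand, counts of methylated reads and of all reads, and the authors' fraction of methylated reads, which equals the quotient of the counts rounded to 3 decimals at every cytosine. The authors mapped the reads to TAIR10 per the labels. The aligner, the removal of duplicate reads and the read filters are not given in the sources used here. The listed coverage ran from 1 to 101 reads, and cytosines without a read were not listed.

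The files list 40539355 (dms4-1), 41118996 (sdr1-1) and 40057184 (dms4-1 sdr1-1) cytosines. Entries with a negative position (32, 31 and 34) or without a context (9, 16 and 14) were left out. Deposited positions were shifted by 1, since this shift paired the acceptor stems of 242 of 532 annotated tRNA genes (45.5%), against 90 without a shift and 152 with a shift of 2. The 5 nuclear chromosomes were used for the comparisons, the chloroplast for the share of unconverted cytosines, and the mitochondrion apart. The depth was 822640975, 850893925 and 688728771 reads summed over nuclear cytosines. A cytosine was used if it had at least 4 reads in all 3 libraries. A weighted level is methylated reads over all reads, with a 95% Wilson interval that covers counting error only.

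Non-overlapping 100-bp bins with at least 4 such cytosines of a context were compared between each pair of libraries by Fisher's exact test (two-sided) on pooled reads. Pooled reads are summed over the cytosines of a bin or gene, so a read counts once for each cytosine it covers. The test takes these counts as independent, which they are not, so its p-values can be too small. Adjustment was by Benjamini-Hochberg over the bins of a context and comparison, 3 contexts by 3 comparisons. A bin was called at an adjusted p under 0.01 and a difference of at least 40 points for CG, 20 for CHG and 10 for CHH. On simulated data at the real depths, with 200 of the bins changed, 0 unchanged bins were called. The simulation drew independent counts from 1 level per bin, without linkage of cytosines in a read, so a count near 0 was built in. Between the strands of a real library, 251 to 529 of 394704 bins passed the CG thresholds. Bins were changed only downward and only where the level allowed the larger drop, so increases and bins of lower level are not covered. Of the bins changed by 50 points in CG, 25 in CHG and 12.5 in CHH, at least 95%, 66% and 56% were recovered, and by 80, 40 and 20 points 100%, at least 96% and at least 83%. To place the double mutant, bins were chosen on the forward strand and measured on the reverse strand. Chance overlap of calls was estimated from independent lists and from simulated unchanged libraries that share sdr1-1.

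Genes came from an annotation of TAIR10.1, which differs from the build in the labels in name and was used for names and neighbourhoods. It was planned to use 1 kb upstream, but 1 kb to each side of a gene was used. It was planned to define pericentromeres by exon density, but the 4 Mb around the centromeres, set at 15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5, were used. Annotated pseudogenes stood in for transposons, whose lengths and superfamilies were not analysed here. Named genes followed a rule set before the data were examined. Per comparison these were the first 5 lower and 5 higher genes by number of called CHH bins and the first 3 each for CG and CHG, with at least 2 bins, besides the list members that passed, the gene in the labels and the longest runs of adjacent bins. Levels of the genes ranked by called bins were pooled over their called bins in that comparison, not over the whole gene. The gene with the Rtf2 domain was not found by name, so it has no value. Members of the lists with called bins were singled out after their values were seen.

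The 6 gene lists, also set before the data were examined, held 14 genes described as methylation targets, 20 of the RNA-directed DNA methylation machinery, 16 of maintenance and removal, 23 of splicing, 6 housekeeping genes and 5 transposon loci. Each gene with its flanks was tested as the bins were, adjusted over all genes and adjusted over the list alone. List medians were ranked among 10000 random lists matched on the mean level of the libraries.

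The alternatives were at least 10 reads per cytosine, 200-bp bins, difference thresholds of 60, 40 and 20 points, thinning to equal depth, leaving out the top 1% of coverage, and requiring at least 50% of the threshold in the same direction on both strands. Levels were also corrected for the chloroplast level and averaged without weights, and the strands used to choose and to measure were exchanged. Scaling the levels to the same genome-wide level before the difference threshold was chosen after seeing the data. It multiplies the level of the second library by the ratio of the genome-wide levels and keeps the p-values. The direction in which it moves the counts is therefore built in. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, numba 0.67.0, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.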

Results

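DNA methylation was measured by whole-genome bisulfite sequencing in mature leaves of 3 Arabidopsis thaliana genotypes: the mutant dms4-1, the mutant sdr1-1 and the double mutant dms4-1 sdr1-1. DMS4 is known as an IWR1-type protein needed for RNA-directed DNA methylation, the pathway in which small RNAs guide methylation to transposons and repeats. The series title concerns a protein with an Rtf2 domain and pre-mRNA splicing. Each genotype was represented by 1 library, so no value below has a replicate error, no difference has a replicate check, and every test compares 2 libraries and not 2 genotypes. No wild-type library was analysed here, so each value is relative to another mutant. The reads listed over nuclear cytosines summed to 822640975 for dms4-1, 850893925 for sdr1-1 and 688728771 for dms4-1 sdr1-1, a mean of 20.3, 20.7 and 17.2 reads per listed cytosine. Of 41528774 nuclear cytosines listed in any library, 28254824 (68.0%) had at least 4 reads in all 3 libraries and were used. Their mean coverage in dms4-1, sdr1-1 and the double mutant was 33.9, 32.6 and 28.1 reads for CG, 31.9, 31.1 and 26.6 for CHG, and 24.7, 25.3 and 21 for CHH, where H is A, C or T.

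The genome-wide levels of the double mutant and sdr1-1 differed by 2.69 points in CG and 2.42 in CHG, which is a ratio of 1.07 and 1.21. The weighted CG level was 37.7% in dms4-1, 36.0% in sdr1-1 and 38.7% in dms4-1 sdr1-1. The CHG level was 13.6%, 11.5% and 13.9% in the same order, and sdr1-1 was the lowest on 5 of 5 chromosomes. The CHH level was 4.31% (95% Wilson interval 4.309 to 4.313) in dms4-1, 4.59% (4.590 to 4.594) in sdr1-1 and 4.53% (4.526 to 4.530) in dms4-1 sdr1-1, but the double mutant lay above sdr1-1 on 2 of 5 chromosomes. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A read also counts once for each cytosine it covers, here and in the tests below. The chloroplast, whose DNA is unmethylated and which gives the share of unconverted cytosines, had CHH levels of 0.838%, 0.717% and 0.795%, with CG and CHG levels between 0.641% and 0.752%. With every cytosine weighted equally, the levels in dms4-1, sdr1-1 and the double mutant lay closer together in CG and CHG, at 31%, 30.1% and 30.8% and at 10.2%, 9.15% and 9.77%. Then sdr1-1 was still lowest in CG and CHG and highest in CHH, but dms4-1 lay above the double mutant in all 3 contexts, with CHH at 3.58% in dms4-1, 3.91% in sdr1-1 and 3.48% in dms4-1 sdr1-1. The order of dms4-1 and the double mutant therefore depended on the weighting.

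The CHH difference between the libraries varied with the feature and with the part of the chromosome. In the arms, the flanks of protein-coding genes (1 kb to each side) had CHH levels of 1.86% in dms4-1, 3.04% in sdr1-1 and 1.68% in dms4-1 sdr1-1. Intergenic sequence farther from genes had 3.91%, 5.91% and 3.73%, so both libraries carrying dms4-1 had 0.662 and 0.632 times the sdr1-1 level, with the same direction on 5 of 5 chromosomes. These levels and ratios are not corrected for the share of unconverted cytosines. Annotated pseudogenes in the pericentromeres, many of which are transposon genes, had 12.1%, 12.5% and 13.2%. Pericentromeric gene flanks (6.47%, 8.19% and 6.55%) and intergenic sequence (10.3%, 11.7% and 10.9%) had the highest level in sdr1-1 on 5 of 5 chromosomes, as in the arms. Bodies of protein-coding genes had 1.33%, 1.28% and 1.21%, near the chloroplast CHH levels of 0.838%, 0.717% and 0.795%. Their order is not corrected for this background, which was highest in dms4-1 and lowest in sdr1-1. CHG went the other way in the pericentromeres, with 41.8% in dms4-1, 34.6% in sdr1-1 and 41.5% in dms4-1 sdr1-1, and was 7.01%, 8.30% and 6.02% in the gene flanks of the arms. CG in the gene flanks of the arms was 22.8%, 20.5% and 22.4%, but 15.5%, 15.1% and 15.0% with every cytosine weighted equally.

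**Figure D1:**
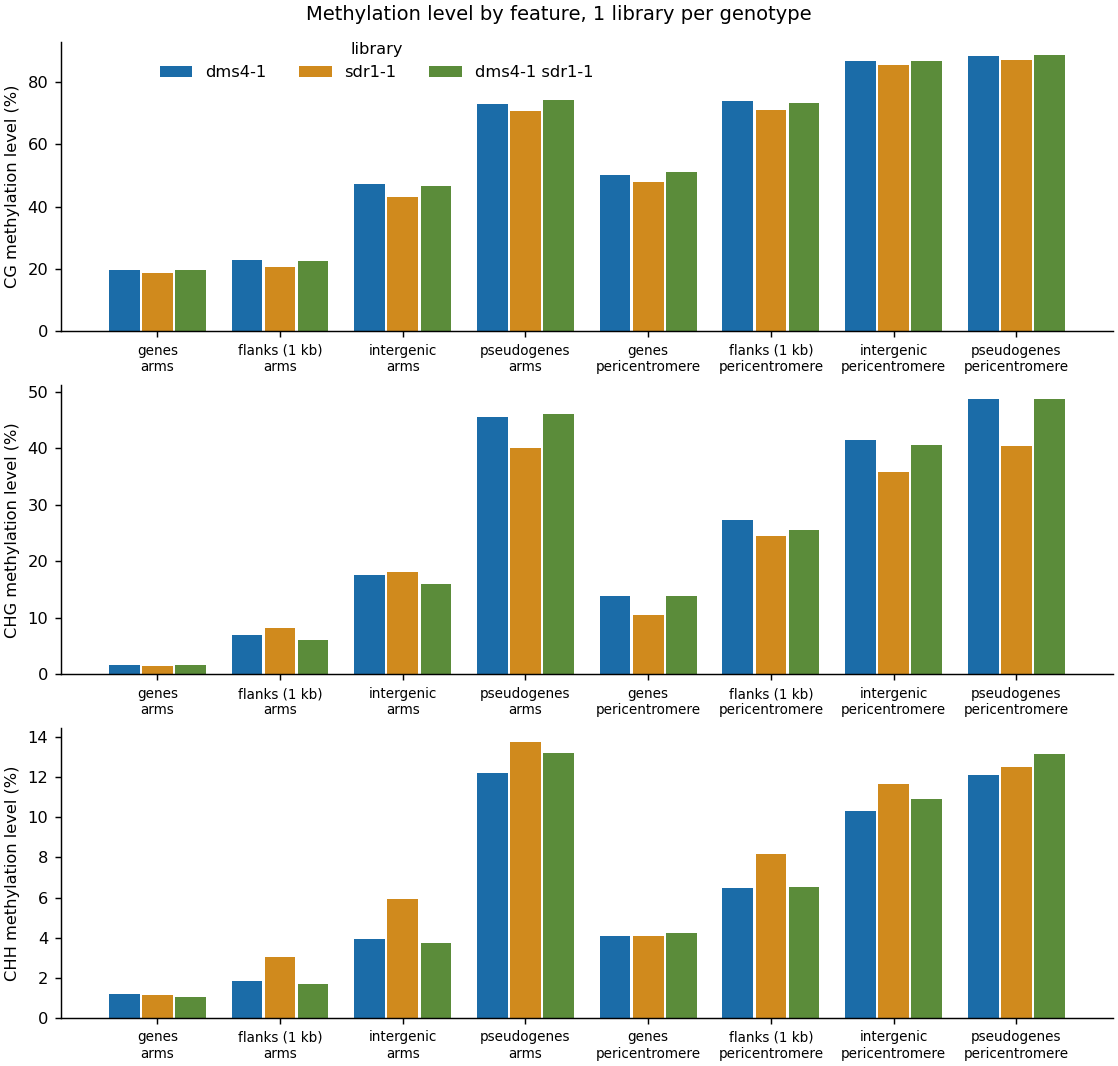
Weighted methylation level (percent, y axis) in CG, CHG and CHH (panels, top to bottom) over features of the chromosome arms and pericentromeres (x axis), with a bar for each library and no error bars, since each genotype had 1 library. In CHH, sdr1-1 stands above the others in flanks and intergenic sequence of the arms, at 3.04% and 5.91%, and in CHG it stands below them in pericentromeric pseudogenes, at 40.4% against 48.8% and 48.8%.

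The comparison of dms4-1 with sdr1-1 asked how the single mutants differ. CHH methylation was lower in dms4-1 in 18480 of 1113775 tested 100-bp bins and higher in 201 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p under 0.01 and a difference of at least 10 points). The median difference of the lower bins was -17.9 points. Flanks of protein-coding genes held 39.7% of the lower bins but 18.6% of the tested ones, and intergenic sequence held 42.9% against 15.6%. Chromosome arms held 79.5% of the lower bins against 84.2% of the tested ones, and pericentromeres held 66.2% of the higher bins against 15.8%. At least 1 lower bin lay in or within 1 kb of 7039 of 37899 annotated genes (18.6%), 4733 of them protein-coding. In the lower bins CG methylation was 88.6% in dms4-1 and 89.3% in sdr1-1 over the 8983 bins also tested in CG, while CHG was 31.9% against 54.7% over the 7001 bins also tested in CHG.

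Of 4419 genes with at least 2 bins of lower CHH in dms4-1, 2979 were protein-coding and 839 pseudogenes, while 4 of the 5 with the most such bins were annotated pseudogenes. Levels of genes ranked by called bins, here and in the other contexts and comparisons, cover the called bins alone and not whole genes. Their gaps therefore follow in part from the call threshold, and the bins of a gene differ between comparisons. AT1G21945 held 24 such bins on chromosome 1 between 7717401 and 7722700 (TAIR10), with 6.65% in dms4-1, 21.5% in sdr1-1 and 8.10% in the double mutant. AT2G34100, annotated as protein-coding, held 24 bins on chromosome 2 between 14402201 and 14412400, with 11%, 26.5% and 11.5%. AT3G47260 held 23 (9.57%, 30.0% and 8.35%), AT2G15940 held 22 (11%, 28.2% and 10.2%) and AT1G55400 held 21 (7.31%, 26.3% and 6.61%), each in the order dms4-1, sdr1-1 and double mutant. Bins of higher CHH were led by the pseudogene AT3G13250, with 10 bins on chromosome 3 between 4277501 and 4282400 at 21.4% in dms4-1, 8.74% in sdr1-1 and 22.3% in the double mutant. Its neighbour AT3G13270 held 3 bins, as did AT4G07810, AT3G31373 and AT1G36500. The longest run of adjacent lower bins spanned 18 bins on chromosome 1 (22163401 to 22165200), with the middle bin in intergenic sequence. CHH there was 8.69% in dms4-1, 22.5% in sdr1-1 and 8.18% in the double mutant. The longest run of higher bins had 2 bins, on chromosome 3 (12260301 to 12260500), at 19%, 1.23% and 3.2%. How reads matching several copies of such elements were treated is not given in the sources used here.

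In CHG, 4543 of 530045 bins were lower in dms4-1 than in sdr1-1 and 5306 were higher (difference of at least 20 points). The directions lay only partly in different features. Of the lower bins, 45.5% were in gene flanks against 8.65% of the tested ones, while 82.6% were in chromosome arms, close to the 82.7% of the tested ones. Of the higher bins, 49.4% were in pseudogenes against 12.5% of the tested ones, and 67.8% in pericentromeres against 17.3%. Intergenic sequence held a large share of both, with 38.2% of the lower and 24.9% of the higher bins against 9.07% of the tested ones. AT2G03330 (11 lower bins on chromosome 2, 1010801 to 1013000) had CHG levels of 21.4% in dms4-1 and 62.9% in sdr1-1, AT3G27470 (8 bins) had 8.53% and 43.4%, and HCF136, a photosystem assembly factor, had 2.86% and 60.1% over 7 bins within its gene and flanks. Higher CHG was led by the pseudogenes AT5G32690 (27 of 364 tested bins, 57.9% against 34.0%), AT3G13250 (19 of 55, 78.9% against 49.7%) and RE2, a Copia-type retroelement (16 of 38, 53.3% against 24.0%). The longest runs were 7 lower bins on chromosome 5 (14300901 to 14301600) and 8 higher bins on chromosome 3 (15859501 to 15860300). The middle bin of the higher run lay in a pseudogene. In these runs dms4-1 had 14.6% and 48.7% and sdr1-1 69.2% and 15.8%. The share of called CHG bins that were lower was 46.1%, and it was 71.1% when the levels of the libraries were first scaled to the same genome-wide level. That scaling raised the sdr1-1 level, so a shift toward lower bins was built in. The share was also 59.0% in 200-bp bins, 89.2% at a difference threshold of 40 points and 38.7% with at least 10 reads per cytosine. Which direction was the more frequent therefore depended on these settings.

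In CG, 1070 of 472615 bins were lower in dms4-1 than in sdr1-1 and 1842 were higher (difference of at least 40 points), mostly inside protein-coding genes, which held 61.7% and 72.8% of them against 60.9% of the tested bins. LHCA2, a light-harvesting protein of photosystem I, held 7 bins of higher CG in dms4-1 on chromosome 3 (22746401 to 22748200), at 75.6% in dms4-1, 23.0% in sdr1-1 and 53.2% in the double mutant. AT1G26380 (5 bins, 81.7%, 25.6% and 52.6%), which held the longest run of higher bins, and AT5G25050 (3 bins, 95.7%, 7.16% and 9.19%) followed. Lower CG was led by AT3G06645 and AT3G43675, which share 7 bins on chromosome 3 (15570901 to 15571800) at 26.4%, 88.6% and 90.8%. AT5G23115 followed with 5 adjacent bins, the middle one in the flank, on chromosome 5 (7777401 to 7777900). They were the longest run, at 19.3%, 89.1% and 5.28%. Between the strands of a single library, 251 to 529 of 394704 bins passed the same CG thresholds, against 2810 and 2855 between dms4-1 and sdr1-1 on the forward and the reverse strand alone, 2375 and 2288 between the double mutant and dms4-1, and 1363 and 1415 between the double mutant and sdr1-1.

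**Figure D2:**
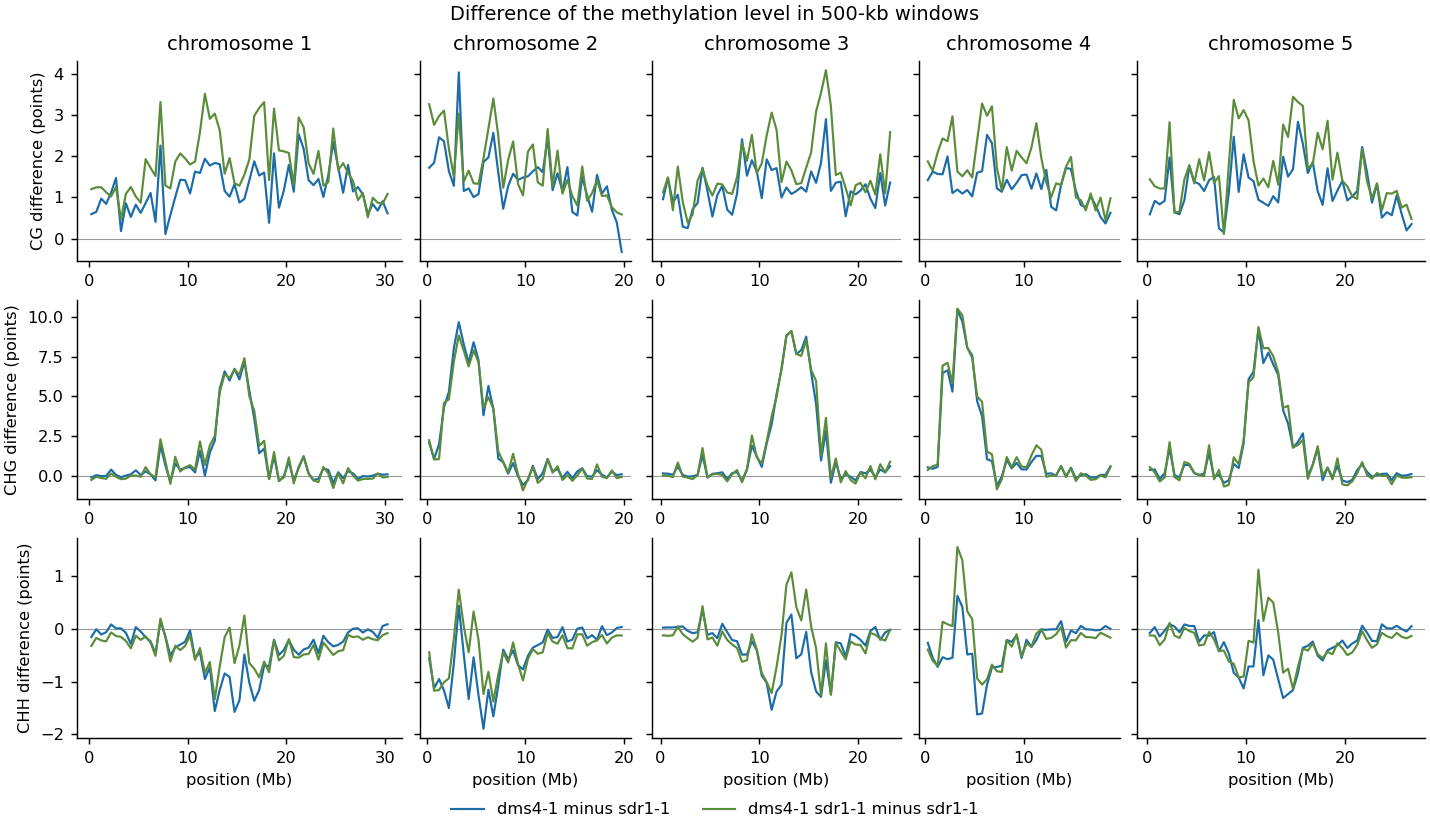
Difference of the weighted methylation level (points, y axis) of dms4-1 (blue) and dms4-1 sdr1-1 (green) from sdr1-1 in 500-kb windows along the 5 chromosomes (x axis, Mb), for CG, CHG and CHH from top to bottom. The CHG difference rises around the centromeres, where the pericentromeric levels were 41.8% and 41.5% against 34.6% in sdr1-1.

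The comparison of the double mutant with sdr1-1 asked what dms4-1 adds to sdr1-1. CHH was lower in the double mutant in 19207 bins and higher in 261, CHG in 5534 and 3461, and CG in 867 and 768. Lower CHH again lay in gene flanks (40.0% of the bins) and intergenic sequence (43.4%). CG methylation was 87.6% in the double mutant and 89.3% in sdr1-1 over the 9187 of these bins also tested in CG. The pseudogenes AT3G47260 (29 bins, 8.85% in the double mutant against 30.3% in sdr1-1), AT2G15940 (24 bins, 10.5% against 28.4%), AT1G21945 (24 bins, 6.98% against 22.8%) and AT4G17820 (22 bins, 12.8% against 34.0%) and the gene AT2G34100 (26 bins, 10.1% against 26.0%) led the lower bins. The longest lower run had 17 bins on chromosome 1 (13148401 to 13150100), with the middle bin in a protein-coding gene, at 9.69% against 25.8%. Higher CHH was led by AT3G13250 (26 bins, 22.6% against 10.3%) and its neighbours AT3G13260 (8 bins) and AT3G13270 (7 bins), then AT3G42535 (3 bins) and AT5G32690 (2 bins). The longest higher run had 4 bins on chromosome 3 (4281701 to 4282100), at 20.1% in the double mutant and 2.93% in sdr1-1.

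CHG was lower in the double mutant than in sdr1-1 at AT2G03330 (11 bins, 17.8% against 61.8%), AT3G44210 (9 bins, 8.78% against 45.0%) and the pseudogene AT3G43586 (9 bins, 33.1% against 58.5%), and the longest lower run was the 7 bins on chromosome 5 named above, at 13.9%. It was higher at the pseudogenes AT5G35935 (27 bins, 66.8% against 38.8%), AT3G13250 (17 bins, 74.3% against 43.0%) and RE2 (16 bins, 52.6% against 26.2%). The longest higher run had 7 bins on chromosome 3 (15859501 to 15860200). CG was lower at AT2G05695 (6 bins, 5.29% against 75.3%) and at the neighbours AT2G21090 and AT2G21100 (5 shared bins, 10.3% against 93.1%). CG was higher at AT3G04265 and AT3G22350 (3 shared bins on chromosome 3, 7901901 to 7902400, 87.4% against 10.5%), which hold the longest higher run, and at LHCA2 (3 bins, 87.0% against 31.9%). The longest lower run was the 5 bins at AT5G23115 named above. The share of called CHG bins that were lower was 61.5%, against 85.4% with scaled levels, 76.0% in 200-bp bins, 95.3% at the stricter threshold and 52.5% with at least 10 reads per cytosine. For CG it was 53.0%, against 64.9% with scaled levels, 63.4% in 200-bp bins and 64.3% at the stricter threshold, and 46.5% with at least 10 reads per cytosine.

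Both comparisons use the sdr1-1 library, so their calls share its chance deviations. Of the bins with lower CHH, 15552 were called in both, which is 84.2% of the dms4-1 calls and 81.0% of the double-mutant calls. Independent lists of these sizes would share 319, which leaves out the shared library. Unchanged libraries simulated at the real depths shared 0, which says little here, since 0 unchanged bins pass the thresholds in simulation. For CHG, 4096 lower and 1628 higher bins were shared (90.2% and 30.7% of the dms4-1 calls; 47.4 and 34.6 for independent lists, 0 and 0 simulated). For CG, 332 lower and 381 higher bins were shared (31% and 20.7% of the dms4-1 calls; 1.96 and 2.99 for independent lists, 0 and 0 simulated). Of the bins with higher CHH, 31 were shared (15.4% of the dms4-1 calls and 11.9% of the double-mutant calls; 0.0471 for independent lists, 0 simulated). The covariance of the differences across bins was 12.4 squared points for CHH, 36.1 for CHG and 20.5 for CG, against 0.926, 2.73 and 3.42 in the simulation. The correlation across bins, which are not independent replicates, was 0.878 for CHH and 0.847 for CHG against 0.439 and 0.468 in the simulation, but for CG it was 0.470 against 0.455, close to that of unchanged libraries. With 1 sdr1-1 library the control could not be split, so part of the overlap may come from that library.

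The comparison of the double mutant with dms4-1 asked whether sdr1-1 changes methylation in a dms4-1 background. Few bins passed the thresholds outside CG. CHH was lower in the double mutant in 44 bins and higher in 91, and CHG in 743 and 134, while CG was lower in 1458 and higher in 1100. No gene held 2 bins of lower CHH, and no lower bins lay side by side. Higher CHH was led by AT3G06645 and AT3G43675 (5 shared bins, 17.2% in the double mutant against 3.47% in dms4-1), where sdr1-1 had 16.2%. The pseudogenes AT2G12040 and AT2G12050 (2 shared bins, 16.8% against 3.33%) and AT5G29408 (2 bins, 24.3% against 8.35%) followed. The share of called CHH bins that were lower was 32.6%, against 42.7% with scaled levels, 45.5% at the stricter threshold and 49.0% in 200-bp bins (25 lower and 26 higher), so the excess of higher bins was lost in the wider bins. For CHG the share was 84.7%, and between 78.5% and 88.1% in the other settings. Shifts under the bin thresholds occurred in both directions over whole features. CHH in annotated pseudogenes was 13.2% in the double mutant and 12.2% in dms4-1, higher on 5 of 5 chromosomes. CHG in the gene flanks of the arms was 6.02% and 7.01%, lower on 5 of 5.

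Lower CHG in the double mutant than in dms4-1 was found most often in intergenic sequence (36.2% of the bins) and gene flanks (29.6%). It was led by AT2G05695 (6 bins, 0.968% against 45.4%), AT2G25050 (6 adjacent bins on chromosome 2, 10658601 to 10659200, 5.79% against 46.1%) and the transcribed pseudogene AT5G28527 (5 bins, 22.6% against 52.4%). Higher CHG was led by AT3G43675 (9 bins, 57.9% against 17.2%), AT3G06645 (8 bins, 58.5% against 16.1%) and ASY2, a meiotic chromosome axis protein (6 bins on chromosome 4, 15549501 to 15550200, 55.6% against 3.0%), which held the longest higher run. Lower CG was led by AT2G05695, a noncoding RNA gene (6 bins on chromosome 2, 5009201 to 5009900, 5.29% against 94.9%), which held the longest lower run, and by AT2G21090 and AT2G21100 (5 shared bins, 9047901 to 9048500, 10.3% against 74.3%). Higher CG was led by AT3G06645 and AT3G43675 (7 shared bins, 90.8% against 26.4%) and AT3G07405 (4 bins, 83.5% against 35.6%). At the AT3G43675 locus dms4-1 was the library apart, at AT2G05695 and ASY2 the double mutant.

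**Figure D3:**
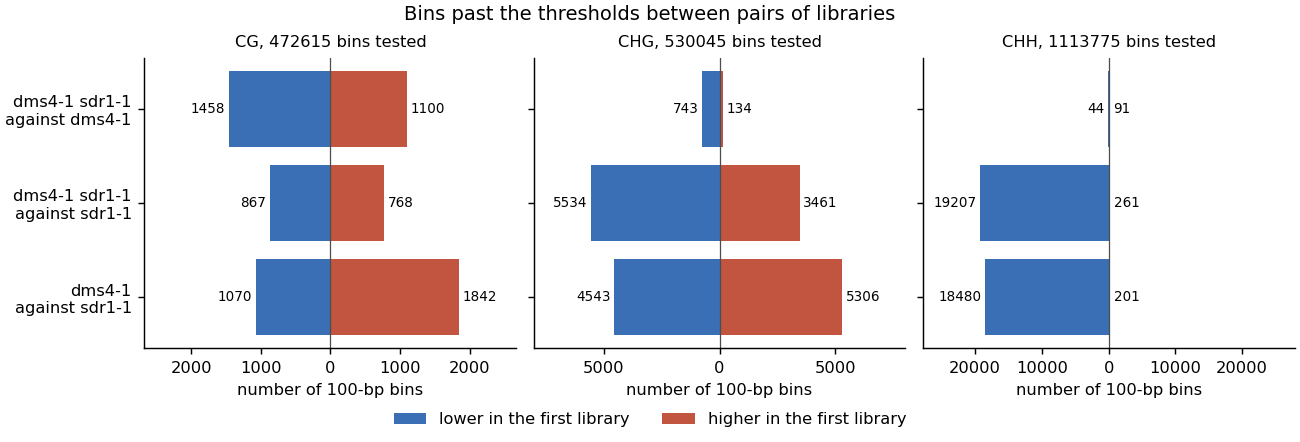
Number of 100-bp bins (x axis, lower to the left and higher to the right of 0) past the thresholds in each comparison of 2 libraries (y axis), for CG, CHG and CHH, each panel with its own linear scale. CHH differed in 18480 and 19207 lower bins in the comparisons with sdr1-1 and in 44 between dms4-1 sdr1-1 and dms4-1.

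To place the double mutant between the single mutants, bins were chosen on the forward strand and levels measured on the reverse strand. In 9647 bins with lower CHH in dms4-1 the reverse-strand level was 6.59% in dms4-1, 20.4% in sdr1-1 and 6.66% (95% Wilson interval 6.63 to 6.70) in the double mutant, whose level was between 6.45% and 7.17% on each of the 5 chromosomes. In 292 bins with higher CHH in dms4-1 the levels were 11%, 10.1% and 11.4%, so the difference chosen on the forward strand was mostly lost on the reverse strand. In 2798 bins with lower CHG the double mutant had 15.8%, against 18.1% in dms4-1 and 52.6% in sdr1-1. In 4472 bins with higher CHG it had 48.3%, against 50.2% and 36.0%. CG differed from this pattern. In 968 bins with lower CG in dms4-1 (27.4% against 67.1% in sdr1-1) the double mutant had 53.7%, and in 1819 bins with higher CG (67.7% against 26.9%) it had 44.3%.

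**Figure D4:**
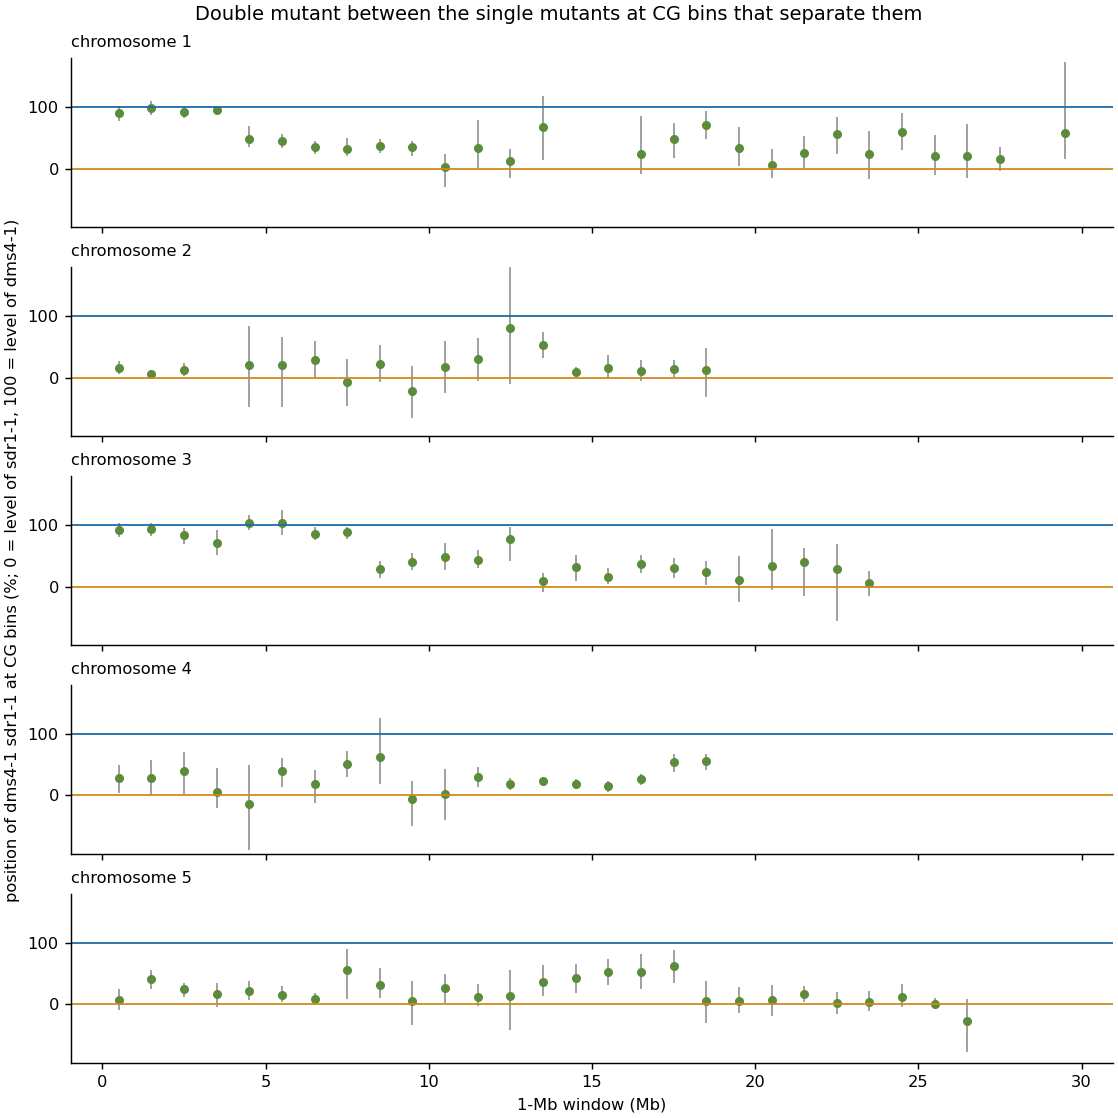
Position of dms4-1 sdr1-1 between the single mutants (y axis, percent; 0 is the level of sdr1-1 and 100 that of dms4-1) in 1-Mb windows along the 5 chromosomes (x axis, Mb), over CG bins chosen on the forward strand and measured on the reverse strand. Points are windows with at least 5 clusters of bins and lines their 95% bootstrap intervals, of which 1 on chromosome 2 (12 to 13 Mb) ends beyond the axis at 309; the windows range from -27.5 to 103.

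Some genes described as targets of DNA methylation had lower CHH in the libraries carrying dms4-1 at short stretches in or near the gene. Of 14 genes in this list, 6 (FWA, MEA, QQS, ROS1, RPP7 and SDC) held a bin with lower CHH in dms4-1 than in sdr1-1, and the same 6 in the double mutant, while 1 (QQS) also held a higher bin in each. The rest held no lower bin, and of all annotated genes 18.6% and 18.7% held one. Whether the list differs from all genes in this share was not tested. SDC is an F-box gene silenced by methylation of upstream repeats. A flank bin (chromosome 2, 7681901 to 7682000) had 360, 602 and 387 reads summed over cytosines in dms4-1, sdr1-1 and the double mutant. Its CHH level was 2.78%, 23.3% and 5.68% in the same order (adjusted exact p = 5.53e-18 for dms4-1 against sdr1-1). In the flank of MEA, an imprinted Polycomb gene, it was 1.47%, 32.1% and 2.94% (chromosome 1, 549701 to 549800, adjusted exact p = 1.73e-12). In the body of FWA, an imprinted homeodomain gene, it was 1.91%, 12.3% and 0.813% over 17 cytosines (chromosome 4, 13038301 to 13038400, adjusted exact p = 2.25e-07). Beside ROS1, which encodes a DNA demethylase, CHH was 0.746%, 18.2% and 2.34% (chromosome 2, 15314901 to 15315000, adjusted exact p = 7.24e-06), and CG in the next bin, in the gene body, was higher at 72.5%, 21.5% and 72.7% (15314801 to 15314900, adjusted exact p = 7.7e-14). At QQS, whose methylation is known to vary between lines, body CG was 67.5%, 3.70% and 66.3% (chromosome 3, 12349301 to 12349400, adjusted exact p = 7.39e-13), and at the resistance gene SNC1 it was 56.4%, 11% and 10.8% (chromosome 4, 9504201 to 9504300, adjusted exact p = 1.11e-28). These members were picked from the list after their values were seen.

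Averaged over whole genes, few list members passed the thresholds. With 1 kb to each side, 127 of 37647 genes were lower in CHH in dms4-1 than in sdr1-1 and 0 were higher, 135 and 0 for the double mutant against sdr1-1, and 0 and 0 for the double mutant against dms4-1. Of the 5 named transposon loci, ONSEN3, a heat-responsive Copia element, was lower in both libraries carrying dms4-1, also with p adjusted over the list alone. Its CHH level was 6.04% in dms4-1, 18.7% in sdr1-1 and 8.46% in the double mutant (adjusted exact p = 5e-193 for dms4-1 against sdr1-1). The median CHH difference of the transposon loci between dms4-1 and sdr1-1 was -4.51 points, at percentile 1.34 among 10000 random lists matched on level, and -4.19 points (percentile 1.91) for the double mutant. The methylation targets had a median of 0.0849 points (percentile 71.9) for dms4-1 and -0.133 (43.0) for the double mutant, and the RNA-directed DNA methylation machinery 0.129 (73.1) and -0.0643 (37.4). The medians of maintenance and removal were 0.112 (56.7) and -0.0710 (37.6), of splicing 0.0927 (43.6) and -0.105 (11.9), and of the housekeeping genes 0.153 (73.0) and 0.0133 (81.2). Apart from the transposon loci, the median CHH levels of the lists lay between 0.817% and 1.16%. They were near the chloroplast levels of 0.838%, 0.717% and 0.795%, so these small differences are not corrected for the background. Over 6 lists, 3 contexts and 3 comparisons, percentiles near an end also occurred elsewhere, though none nearer than 1.34. None was adjusted for their number. Among them, the double mutant against sdr1-1 had 97.6 for housekeeping genes and 1.67 for transposon loci in CG. It also had 98.5 for the RNA-directed DNA methylation machinery in CHG. Against dms4-1 it had 96.6 for methylation targets in CG and 96.2 for splicing in CHG. For dms4-1 against sdr1-1, methylation targets had 3.85 in CG. No member of the other lists passed in any context or comparison, whether adjusted over all genes or adjusted over the list alone. Without the size threshold, adjusted p alone put 7446 of all genes lower and 2588 higher in CHH in dms4-1 than in sdr1-1. In the lists these were 2 and 2 of the RNA-directed DNA methylation machinery, 2 and 1 of maintenance and removal, 2 and 0 of splicing, 0 and 0 of the housekeeping genes, 4 and 0 of the transposon loci, and 5 and 1 of the methylation targets, the lower ones including SDC (1.40% against 4.11%) and QQS (6.33% against 10.9%).

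In the other lists the number of genes with a bin of lower CHH ranged from none to all members, to be read beside 18.6% of all annotated genes in dms4-1 and 18.7% in the double mutant, and no difference from that share was tested. Of 20 genes of the RNA-directed DNA methylation machinery, 4 (DCL3, DMS3, NRPD2 and SUVH9) held a bin with lower CHH in each library carrying dms4-1 than in sdr1-1 and 0 held a higher one. In the flank of SUVH9, a protein that recruits RNA polymerase to methylated DNA, CHH was 2.59% in dms4-1, 30.3% in sdr1-1 and 5.24% in the double mutant (adjusted exact p = 4.84e-25). DMS4 itself, the gene mutated in dms4-1, had CG levels over the gene and its flanks of 21.4%, 20.2% and 20.5%. Its CHH levels, near those of the chloroplast, were 1.06%, 0.772% and 0.777%. In its body 1 bin of 4 cytosines had higher CG in the double mutant than in sdr1-1, at 96.0% against 45.2%, with 84.0% in dms4-1 (chromosome 2, 12910901 to 12911000, adjusted exact p = 7.12e-11). These values do not check the genotype labels, because the files give no bases. Of 16 genes of methylation maintenance and removal, 3 (ROS1, VIM1 and VIM3) held lower CHH in each library carrying dms4-1. Beside VIM1, a factor of CG maintenance, 1 bin had 1.61%, 46.6% and 2.94% (adjusted exact p = 5.04e-18). Of 23 splicing factors, 4 (SAD1, SKIP, SR45 and STA1) held lower CHH in dms4-1 and 5 in the double mutant (the same 4 and PRP31). STA1 is a splicing factor homologous to yeast Prp6. In a flank bin (chromosome 4, 1515201 to 1515300) CHH was 1.88%, 21.7% and 0.589% (adjusted exact p = 2.53e-43). The bin had 959, 950 and 849 reads summed over cytosines. Of 6 housekeeping genes, 0 held a CHH or CHG bin in any comparison, but CG in the body differed at ACT2 (40.9%, 0.613% and 45.0%) and TUB2 (68.9%, 20% and 26.5%). All 5 transposon loci held a lower CHH bin in dms4-1 and 4 in the double mutant. Between the double mutant and dms4-1, 0 members of any list held a CHH bin. In CG, a lower bin in the double mutant was held by SNC1, DCL3, DRD1, MORC6, RDR2, MET1, PRP8B, RS31, SR34 and TUB2 and a higher one by DRD1, MORC6 and MET1, against 4.51% and 3.76% of all annotated genes. A CHG bin was lower in the flank of the Copia element EVD, at 46.3% against 87.8% in dms4-1 and 32.2% in sdr1-1 (chromosome 5, 5635501 to 5635600, adjusted exact p = 0.00802 against dms4-1). A CHG bin was higher in the double mutant at DRM2, the de novo methyltransferase, at 24.8% against 0.735% in dms4-1 and 2.79% in sdr1-1 (chromosome 5, 4716201 to 4716300, adjusted exact p = 3.83e-16 against dms4-1).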

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

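All tests in this part were chosen after the results were seen. The mitochondrial chromosome lies outside the comparisons, and its CG level stood above the chloroplast's, at 27.2% in dms4-1, 19.8% in sdr1-1 and 25.9% in dms4-1 sdr1-1 against 0.722%, 0.641% and 0.675%. Unconverted cytosines would give equal levels in all contexts, but the mitochondrial CG level was at least 5.57 times the CHH level in each library, so they are argued against. Reads from a nuclear copy of mitochondrial DNA are a candidate explanation. The shares of nuclear reads implied by CG, CHG and CHH lay close together within each library, with a largest ratio of 1.2. These shares, from 23.9% to 40.3%, take the pericentromeric level as that of the copy. In the copy known near the centromere of chromosome 2 CG was 50.5%, 42.7% and 49.5%, against 86.3%, 85.0% and 86.4% in the sequence to its left. In the window of the copy 26977 cytosines were listed, against 86133 in the equally wide window to its left. The level of the copy thus rests on fewer cytosines. No biological explanation was tested.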

How the results depend on the processing

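Scaling the levels was chosen after seeing the data; the other alternatives were set before. Thinning to equal depth and leaving out the top 1% of coverage each kept all 18 counts of bins within 1.5 times. No paired analysis was possible because each genotype had 1 library, and no library could be left out for the same reason. Intervals cover counting error only, and the unmoved results numbered 6 of 18 for 200-bp bins, 15 for both strands and 16 for scaled levels. The cause of each change below was not tested, except that stricter thresholds and higher coverage leave fewer bins by construction. A region also holds fewer 200-bp bins than 100-bp bins, so counts in these widths are not directly comparable.

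With at least 10 reads per cytosine the levels in dms4-1, sdr1-1 and dms4-1 sdr1-1 were 39.1%, 37.9% and 40.3% for CG, 14.4%, 12.3% and 14.7% for CHG and 4.59%, 4.98% and 4.90% for CHH. Corrected for the chloroplast they were 37.2%, 35.6% and 38.3%, 13.0%, 10.9% and 13.3%, and 3.5%, 3.90% and 3.76%. Unweighted they were 31%, 30.1% and 30.8%, 10.2%, 9.15% and 9.77%, and 3.58%, 3.91% and 3.48%, which places dms4-1 above the double mutant.

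With at least 10 reads per cytosine, CG bins numbered 629 lower and 535 higher in the double mutant than in dms4-1, 342 and 394 against sdr1-1, and 462 and 953 in dms4-1 against sdr1-1. Lower CHG bins numbered 3151 in the double mutant and 2586 in dms4-1 against sdr1-1. CHH bins numbered 26 and 56 between the double mutant and dms4-1, and the lower ones 12591 in the double mutant and 12227 in dms4-1 against sdr1-1.

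In 200-bp bins, CG numbered 909 lower and 546 higher in the double mutant than in dms4-1, 393 higher than in sdr1-1, and 640 and 1010 in dms4-1 against sdr1-1. Higher CHG bins numbered 85, 1799 and 3242 in the comparisons double mutant against dms4-1, double mutant against sdr1-1 and dms4-1 against sdr1-1. CHH numbered 25 lower and 26 higher in the first, and 47 and 38 higher in the others.

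With the stricter thresholds, in the same order of comparisons, CG bins numbered 397 lower and 233 higher, 240 and 133, and 231 and 368. CHG bins numbered 95 and 26, 2237 and 110, and 1758 and 213, so in dms4-1 against sdr1-1 the lower ones became the more frequent. CHH bins numbered 5 and 6, 7996 and 7, and 7610 and 10.

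With the same direction on both strands, CHH bins numbered 24 lower in the double mutant than in dms4-1, and 153 and 114 higher in the double mutant and dms4-1 than in sdr1-1. With scaled levels, higher CHG bins numbered 1146 in the double mutant and 2251 in dms4-1 against sdr1-1.

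The CHH level of the double mutant in bins lower in dms4-1 was 7.09% chosen on the reverse strand and 7.52% with at least 10 reads, against 6.66%. In bins higher in dms4-1 it was 11.1% and 12.2%, against 11.4%.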

Other observations

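All tests in this part were chosen after the results were seen. For the test on windows of equal coverage, the criterion was written before its own value was seen, but for a pattern already seen. CHH methylation in intergenic sequence of the arms was lower in dms4-1 than in sdr1-1 in each sequence class, with 0.690 times the sdr1-1 level in dms4-1 where CA starts the context (4.85% against 7.04%), 0.657 times for CT (4.12% against 6.28%) and 0.564 times for CC (1.40% against 2.49%). These ratios are not corrected for the chloroplast CHH level, which was 0.838% in dms4-1 and 0.717% in sdr1-1. The CC levels lie nearest to it, so the classes cannot be ranked by these ratios. The bins with lower CHG in dms4-1 than in sdr1-1 had lower CHH as well, at 3.47% against 22.6% in sdr1-1 and 3.52% in the double mutant over 4471 bins. The bins with higher CHG had CHH at 10.9% in dms4-1, 9.48% in sdr1-1 and 11% in the double mutant over 5290 bins.

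Outside CHH, some gene lists held members in both directions and others in 1 direction only, as picked after their values were seen. Of all annotated genes, 5.93% held a higher and 3.4% a lower CG bin in dms4-1 than in sdr1-1, and 7.82% and 8.31% a CHG bin, and no list was tested against these shares. In CG, 7 of 20 genes of the RNA-directed DNA methylation machinery held a higher bin in dms4-1 than in sdr1-1 and 3 a lower one, among them MORC6 in each, a helper of silencing. Of 23 splicing factors, 4 held a higher CG bin and 2 a lower one, and of 16 genes of maintenance and removal, 2 and 3, with MOM1, a silencing factor, among the lower. In CHG, 4 of 14 methylation targets (IBM1, QQS, RPP7 and SNC1) held a higher bin in dms4-1 and 1 (RPP7) a lower one. Of 5 transposon loci 1 (EVD) held a higher bin and 2 (ATMU1 and ONSEN3) a lower one. One-sided in CG were the methylation targets (4 higher, 0 lower) and the housekeeping genes (2 and 0). In CHG these were splicing (0 higher, 2 lower), the RNA-directed DNA methylation machinery (0 and 1) and maintenance and removal (1 and 0).

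CHG in the pericentromeres was 34.6% in sdr1-1, against 41.8% in dms4-1 and 41.5% in the double mutant. A different share of unconverted cytosines is argued against, because chloroplast CHG differed by 0.105 points between dms4-1 and sdr1-1 and pericentromeric CHG by 7.12. A loss of methylated reads from sdr1-1 stays open for a share of the difference. As the whole cause, a loss equal in CG and CHG is argued against. The highest odds ratio of a chromosome was 1.13 for CG and the lowest 1.28 for CHG. CG still moved with CHG, with an odds ratio of at least 1.107 on each chromosome, and a loss that spares CG was not tested. CHH went the other way, with odds ratios of dms4-1 over sdr1-1 between 0.910 and 0.959 on the chromosomes. For the double mutant over sdr1-1 they lay between 0.974 and 1.040. Unequal coverage stays open for a share of the difference, which was 4.75 points in the 49 windows with the most equal coverage and higher in dms4-1 in 49 of 49. Genotype also stays open, untested with 1 library each and no wild type.

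At CG bins that separate the single mutants the double mutant was 37.3% (95% bootstrap interval 35.1 to 39.6) of the way from sdr1-1 to dms4-1. With borders drawn after the data were seen, it was at 93.5% (87.8 to 98.8) on the first 4 Mb of chromosome 1 and 38.0% (33.0 to 43.0) from 4 to 10 Mb, 90.0% (85.1 to 94.9) on the first 8 Mb of chromosome 3 and 33.4% (27.6 to 39.3) from there to 19 Mb, 16.1% (10.5 to 21.6), 28.3% (23.5 to 33.2) and 22.8% (17.7 to 28.1) on chromosomes 2, 4 and 5, and 5.92% (-1.18 to 13.0) on chromosome 5 from 18 to 27 Mb. The same position everywhere is argued against by a spread between 1-Mb windows of 29.0. It was at most 17.1 in 10000 shuffles of 2215 clusters (permutation p = 0.0001, the smallest they can give). A library mixed with DNA of a single mutant would take the same position everywhere only if the double mutant itself did. If the double mutant varies along the chromosomes, a mixture can keep the spread, so the shuffles cannot exclude it. Blocks inherited from the parents of the cross may lie behind the pattern, as a hypothesis in which the intermediate values need blocks from both parents. The 1 Mb around DMS4, where such blocks would put the double mutant near dms4-1, was at 69.4% (30.7 to 116, 14 clusters), too wide to decide, and the files give no bases to check parentage.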
